A study of Mus musculus with 2 samples.

How the data were processed

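The series holds long-read RNA sequencing of adrenal gland from male B6CASTF1/J mice aged 10 days, with 1 group and 2 biological replicates. Per the labels, the samples were total RNA, replicate 2 started from 1 µg, and spike-in RNAs were added. The labels name the animal of replicate 2 in different ways and give both samples 1 donor, so whether the libraries come from separate animals is unclear. The p values of single genes measure only the spread between reads of these 2 samples. Those of the spike-ins and of isoform length measure the spread between spike-ins and between genes. No p value here measures the spread between animals. With 1 group, no comparison between conditions exists; the replicates were compared with each other to give the size of the replicate error. No paired analysis was possible because the design has no 2 conditions.

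The deposited tables give counts, the raw number of long reads assigned to each transcript model in 1 library, with no normalization. The deposited tables also give the number of exons and the spliced length of each model in bases, and the deposited annotations give the start and end of each model on the mouse genome build mm10 (other unit: bases and 1-based positions). The models are the annotated transcripts of GENCODE M21, ERCC spike-ins and models added by TALON, and were numbered separately in each library. The versions of the aligner and of TALON are not given in the sources used here. Each model carries 1 of 7 classes: Known, ISM (incomplete splice match), NIC (an unannotated combination of annotated splice sites), NNC (an unannotated splice site), Genomic (within a gene, mostly single-exon), Antisense and Intergenic.

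Replicate 1 held 971827 reads in 107755 models and replicate 2 held 1407511 reads in 137106 models, with 927914 and 1303420 reads on annotated genes. Of these, 15825 and 17409 genes had reads. Spike-ins took 1.57% and 2.50% of reads, and mitochondrially encoded genes 0.097% and 0.151% of reads on annotated genes. The mean length of the model of a read was 2335 nt and 1904 nt. In replicate 1 62.6% of models had 1 read, and in replicate 2 60.5%. A count of 0 allows up to 3 reads, or 3.23 CPM in replicate 1 and 2.30 CPM in replicate 2. Intervals are exact Poisson for reads of a gene and Clopper-Pearson for shares, at 95%; they and the floor cover counting error only, since reads made after PCR are not independent molecules.

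Gene reads are the sum over all models of the gene, and CPM is reads per 1000000 reads on annotated nuclear and mitochondrial genes, without spike-ins and unannotated loci. Levels are given as mean ± SD over both replicates. Genes with 10 or more reads over both libraries were tested with a two-sided Fisher's exact test of the gene's reads against all other gene reads (scipy 1.17.1), with Benjamini-Hochberg adjustment and a threshold of 0.05; 0.5 reads were added before the log2 ratio. For each of 19 gene lists, the median log2 ratio of the tested members was ranked among 10000 random lists matched in 20 bins of mean expression. TMM factors (edgeR 4.0.16) were 1.10 and 0.913, and DESeq2 1.42.0 size factors were 0.928 and 1.08. The biological coefficient of variation estimated by edgeR was 0.414. Transcript length and GC content are those of the annotated transcript with most reads in the gene. Correlations used 100000 permutations.

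Isoform shares used reads of annotated transcripts in genes with 20 or more such reads in each library; a gene had 2 or more isoforms in use when its second isoform took 20% or more in both. Usage was compared with a Fisher's exact test of the top isoform against all others. Unannotated models were matched between libraries by chromosome, strand and all introns. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 and in R 4.3.3, and plots drawn with matplotlib 3.10.9.

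The lists, tests and alternatives were fixed before the data were examined, except where stated. The fixed lists were steroidogenesis, zona glomerulosa, zona fasciculata, X-zone, chromaffin medulla, cholesterol synthesis and uptake, capsule and mesenchyme, endothelium, macrophage, erythroid, Schwann and glia, adipose, kidney, liver, proliferation, immediate early and stress, imprinted and fetal growth, sex chromosomes, and alternative splicing. Further liver, brown fat, skeletal muscle, bone and neutrophil granule lists were added after the data were seen. Genes were named by these rules: the 20 with the highest mean CPM, with mitochondrial genes apart; members of the fixed lists, up to the 6 with the highest mean CPM in the lists for other tissues and processes; the 10 with the largest ratio in each direction at a mean of 20 CPM or more; the 15 most-read genes with 2 or more isoforms in use and the list members with enough reads; the 10 NIC and 10 NNC chains with most reads in the smaller library, and those with 5 or more reads in both in a steroidogenesis or medulla gene; and the 5 unannotated loci with most reads in both. Cox8b and the genes with single-exon fragments outside these rules, and the spike-in length of 900 nt, were chosen after their values were seen. A few genes that these rules select are not reported here.

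The gene and isoform tests were tested on simulated data, with reads drawn at the measured levels or shares with counting noise alone. Of 200 changed genes among 11650, 36.0% were called at a 2-fold change and 82.0% at an 8-fold change, or 64.3% and 100.0% at a mean of 20 CPM or more, and 7 unchanged genes were called. Isoform shifts of 10, 20 and 40 percentage points were called in 26.9%, 50.7% and 92.4% of changed genes. For the lists no reads were drawn, and 10 genes picked at random kept their measured log2 ratios. Of such lists, 83.0% of those shifted by 1 on the log2 scale lay outside the middle 95%. So did 5.0% of unshifted ones, a share that the random draw sets in advance.

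The alternatives tried were other scalings and denominators, other read minimums, annotated models only, counts without Genomic or single-exon models, overlapping genes counted together, a minimum size of the difference, random lists matched on length, removal of length and GC trends, other isoform definitions and leaving out each replicate. Splice-site sequence, parental alleles and priming on A-rich stretches were not analysed here, and no reads were assigned to the other spike-ins that the labels name. Reads on ERCC spike-ins were left out of gene comparisons, and annotated genes on unplaced contigs were kept.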

Results

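The adrenal glands of 10-day-old male B6CASTF1/J mice, an F1 hybrid strain, gave 2 libraries rich in transcripts of both the steroid-making cortex and the catecholamine-making medulla. Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, reached 7433 ± 13.3 CPM (counts per 1000000 reads on annotated genes; mean ± SD, n = 2 throughout) and ranked the third among all genes. The later enzymes Cyp21a1 (5805 ± 3164 CPM), Hsd3b1 (4258 ± 1749 CPM) and Cyp11b1 (3720 ± 1896 CPM) and the cholesterol carrier Star (3688 ± 994 CPM) were also among the 20 most abundant genes. Chgb and Chga, proteins of the secretory granules of chromaffin cells, reached 3107 ± 1622 and 3061 ± 1184 CPM, and Th, the first enzyme of catecholamine synthesis, reached 1673 ± 911 CPM. Liver-type and brown-fat-type transcripts were as abundant as these, with Alb (serum albumin) at 6875 ± 2575 CPM, Ahsg at 4441 ± 3950 CPM, Apoa1 at 3184 ± 2664 CPM and the uncoupling protein Ucp1 at 3689 ± 1078 CPM.

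Each of the 19 steroidogenesis genes had 10 CPM or more in both libraries, and together they took 30152 ± 8128 CPM. Cyp17a1, which cortisol synthesis needs, had 20.6 ± 7.44 CPM. The ACTH receptor Mc2r (50.5 ± 19.7 CPM) and its partner Mrap (297 ± 35.8 CPM) were detected in both libraries, as were the regulator Nr5a1 (443 ± 52.9 CPM) and the lipoprotein receptor Scarb1 (1247 ± 94.6 CPM). Markers of each cortical zone were present. The outer zona glomerulosa was represented by the potassium channel Kcnk3 (1358 ± 773 CPM), the aldosterone synthase Cyp11b2 (423 ± 358 CPM) and Wnt4 (191 ± 28.4 CPM), the zona fasciculata by Akr1b7 (1952 ± 526 CPM) and Abcb1b (402 ± 149.5 CPM), and the inner X-zone by Akr1c18 (475 ± 136 CPM) and Cyp2f2 (286 ± 126 CPM). The other 2 X-zone genes, Pik3c2g and Thrb, had 3 and 1 reads and 4 and 6 reads in replicates 1 and 2.

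All 21 chromaffin medulla genes had reads in both libraries, and 17 of them had 10 CPM or more in each. Pnmt, which converts noradrenaline to adrenaline, reached 673 ± 48.3 CPM, Scg2 969 ± 703 CPM, Npy 320 ± 213 CPM and Dbh 214 ± 115 CPM. The transcription factor Phox2a (16.4 ± 1.81 CPM) and the synaptic gene Syt1 (4.46 ± 0.207 CPM) were much less abundant. By the mean of both libraries the most abundant gene was Trf, which encodes the iron carrier transferrin (12869 ± 6896 CPM), and the second was Apoe (7910 ± 6154 CPM), an order set by replicate 2 (17746 and 12262 CPM). In replicate 1 Trf (7993 CPM) lay below Cyp21a1 (8043 CPM), and Apoe had 3559 CPM. Also among the 20 most abundant genes were the energy metabolism genes Atp5b, Atp5a1, Uqcrc1 and Aldoa, the carbonic anhydrase Car3, the G protein gene Gnas and the ubiquitin gene Ubb, between 3157 ± 749 CPM for Aldoa and 6459 ± 451 CPM for Atp5b. Of the mitochondrially encoded genes, counted apart, mt-Co1 had most reads (541 ± 78.8 CPM).

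A mean of 10 CPM or more was reached by 9224 genes, of which 8007 reached it in both libraries. Of the 7 kidney markers, Aqp2 had 5 reads in each library and the others had 0, which allows up to 3.23 CPM in replicate 1 and 2.30 CPM in replicate 2. The labelled male sex was matched by the reads: Xist, the RNA of the inactive X chromosome, had 0 reads in both libraries, and the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d had 87, 44, 16 and 2 reads in replicate 1 and 81, 60, 16 and 2 in replicate 2. Counting only reads of annotated transcripts would remove most of Hsd3b1: its main model, with 4 exons on chromosome 3 from 98852194 to 98858341 of mm10, covers part of an annotated intron chain and held 4050 of the 5098 Hsd3b1 reads of replicate 1 and 2949 of the 3938 of replicate 2, against 11 and 12 reads on annotated transcripts.

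**Figure D1:**
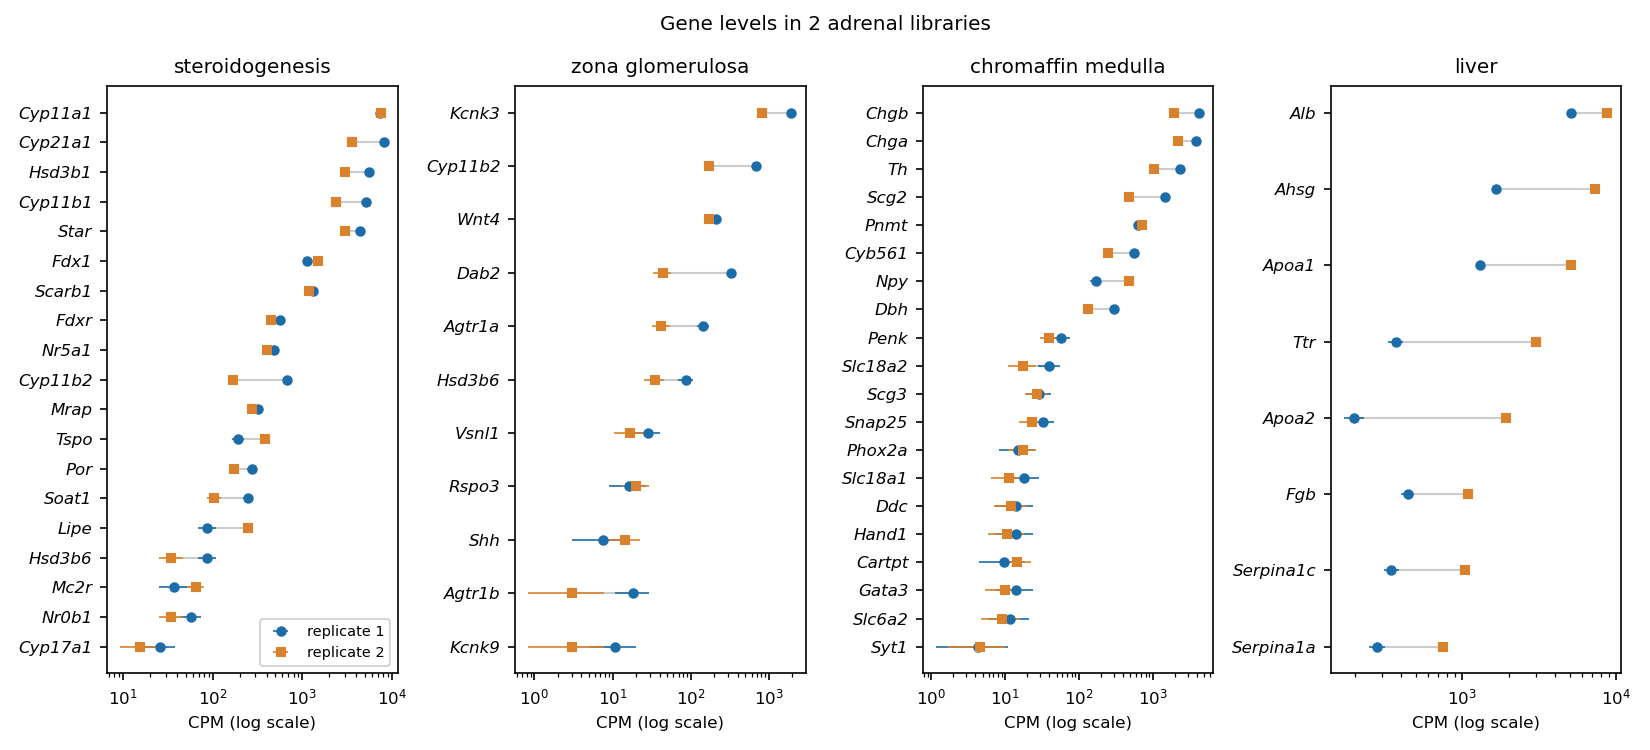
Level of members of 4 gene lists (steroidogenesis, zona glomerulosa, chromaffin medulla and liver) in the 2 libraries, in CPM on a log axis; bars are exact Poisson 95% counting intervals. All 8 liver genes lie higher in replicate 2, and Cyp11b2 (676 and 170 CPM) and Dab2 (332 and 43.7 CPM) lie lower.

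The 2 replicates differed in their cortical and medullary transcripts. In the zona glomerulosa list, 6 of 11 tested genes were lower in replicate 2 and 0 were higher: Cyp11b2, Dab2, Agtr1a and Agtr1b (the angiotensin receptors), Hsd3b6 and Kcnk3. The level of Dab2 in replicate 2 was 0.132 times that in replicate 1 (adjusted p = 9.92e-62, Fisher's exact test, 308 and 57 reads), and that of Cyp11b2 was 0.251 times (adjusted p = 5.03e-79). In the steroidogenesis list, 12 of 19 genes were lower in replicate 2, among them Cyp21a1 (0.444 times), Cyp11b1 (0.470 times), Hsd3b1 (0.550 times) and Star (0.680 times), and 4 were higher (Fdx1, Lipe, Tspo and Mc2r). Cyp11a1 had equal totals (7423 and 7442 CPM, adjusted p = 0.945, exact), but 5152 of 6888 and 3706 of 9700 of its reads (74.8% and 38.2%) lay on annotated transcripts. In the zona fasciculata list 3 of 5 genes were lower (Cyp11b1, Akr1b7 and Abcb1b) and Mc2r was higher, and of 3 tested X-zone genes Akr1c18 and Cyp2f2 were lower.

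In the chromaffin medulla list, 8 of 21 genes were lower in replicate 2, among them Chgb (0.461 times), Chga (0.570 times), Th (0.444 times), Scg2 (0.322 times) and Dbh (0.449 times), while Npy was 2.78-fold higher. Against the ratio expected from transcript length 0 genes of this list were higher and 7 lower, and the excess of Npy, with a transcript of 566 nt, no longer passed (log2 ratio 1.47 as measured and 0.046 against that ratio). In the endothelium list, 5 of 9 genes were lower, among them Plvap (0.361 times) and Pecam1 (0.470 times), and Egfl7 was 1.39-fold higher, which became 1 lower and 1 higher against the ratio expected from transcript length.

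Liver and globin transcripts lay the other way. All 8 liver genes were higher in replicate 2, from 1.72-fold for Alb to 8.22-fold for Ttr and 9.77-fold for Apoa2, and their sum was 9639.9 CPM in replicate 1 and 28829.5 CPM in replicate 2. The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were 4.06-fold, 3.78-fold, 3.18-fold and 3.71-fold higher. Alas2, the first enzyme of haem synthesis in red cells, was 0.571 times its level in replicate 1 (adjusted p = 0.0018, Fisher's exact test). This call was lost with TMM scaling and against the ratio expected from transcript length, where the 4 globin genes stayed higher. Removal of the trends with length and GC content lowered the median log2 ratio of the erythroid list from 1.88 to 0.87. Of 9 macrophage genes, Lyz2 (2.87-fold) and Cd74 (1.77-fold) were higher, and of 7 tested capsule and mesenchyme genes, the collagens Col1a1 (2.83-fold) and Col3a1 (1.54-fold) were. In the adipose list Cfd (3.27-fold), Retn (6.05-fold), Adipoq, Cidea and Fabp4 were higher and Ucp1 lower (0.658 times).

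The other fixed lists were mixed. Of 11 immediate early and stress genes Jun, Egr1, Nr4a1 and Zfp36 were higher in replicate 2 and Dusp1 lower, and of 17 imprinted and fetal growth genes Igf2, H19, Meg3 and Grb10 were higher and Dlk1, Cdkn1c, Mest and Ndn lower. Of 19 cholesterol genes 4 were lower (Dhcr7, Msmo1, Hmgcs1 and Idi1) and 0 higher, a split that became 2 and 2 with TMM scaling. Of 8 proliferation genes Mcm2 and Ccnb1 were lower. Of 34 genes known for alternative splicing 8 were higher and 10 lower, which became 11 and 8 with TMM scaling, 9 and 4 against the ratio expected from transcript length and 6 and 14 with annotated models only. Among the Schwann and glia genes S100b was higher, 1 of 3 tested sex chromosome genes (Eif2s3y) was lower, and the single kidney gene tested did not pass.

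Of the 19 lists, 5 had a median log2 ratio outside the middle 95% of 10000 random lists of equal size and expression: zona glomerulosa (median -1.33, percentile 0.01), steroidogenesis (-0.56, percentile 1.74), liver (1.77, percentile 99.96), erythroid (1.88, percentile 99.8) and macrophage (0.63, percentile 98.4). The percentiles of the others were 7.57 for chromaffin medulla, 11.6 for zona fasciculata, 12.6 for X-zone, 3.98 for endothelium, 89.85 for capsule and mesenchyme, 88.8 for Schwann and glia, 90.6 for adipose, 25.025 for kidney, 48.8 for cholesterol, 50.5 for proliferation, 92.6 for immediate early and stress, 67.7 for imprinted and fetal growth, 34.0 for sex chromosomes and 71.7 for splicing. With p values adjusted over the list alone, the lower genes numbered 13 for steroidogenesis, 8 for zona glomerulosa and 4 for zona fasciculata, and the other lists kept their counts. After removal of the trends with transcript length and GC content, steroidogenesis moved to percentile 6.98, endothelium to 25.15 and macrophage to 94.2. That removal put chromaffin medulla (1.57), zona fasciculata (1.65) and X-zone (2.13) outside the middle 95%. Against random lists also matched on length, erythroid moved to 92.4 and immediate early and stress to 98.8. TMM scaling adds 0.26 to every log2 ratio, which left 8 steroidogenesis genes lower and 5 higher (Nr5a1 and Scarb1 at 0.019 and 0.11, no longer lower), 2 endothelium genes lower, 5 macrophage genes higher and 0 sex chromosome genes lower. Against the ratio expected from transcript length 8 steroidogenesis genes were lower and 4 higher, 2 cholesterol genes lower and 2 higher, 3 adipose genes lower and 5 higher, and 0 erythroid genes lower. The ratios of Fdx1 and Fabp4 changed sign with the ratio expected from transcript length, that of Mc2r with annotated models only, and without Genomic models 0 Schwann and glia genes were higher.

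Beyond the lists, the genes most in excess in replicate 2 included a small nucleolar RNA, a nuclear RNA and a bone transcript. The small nucleolar RNA Snord13 had 0 and 238 reads (at least 56.5-fold higher in replicate 2, against a floor of 3 reads per library), and the nuclear RNA Malat1 was 52.9-fold higher (23 and 1708 reads). Bglap, which encodes the bone protein osteocalcin and has near-identical copies that leave its reads uncertain, had 0 and 77 reads (at least 18.3-fold), and Pdap1 had 0 and 60 reads (at least 14.2-fold). The genes most in excess in replicate 1 included the endocytic adaptor Dab2 (7.59-fold), the amino acid transporter Slc7a5 (8.29-fold, 59 and 10 reads), Git1 (9.27-fold, 66 and 10 reads), Lrch4 (9.83-fold), Rhbdl1 (11.2-fold), Coro7 (8.19-fold), Sorbs3 (7.22-fold) and Peg13 (7.73-fold, 33 and 6 reads), an imprinted RNA that lies within Trappc9.

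Several of these 20 genes have few reads on annotated transcripts or reads of uncertain origin. Annotated transcripts held 2 of 72 and 0 of 14 reads of Sorbs3 and 16 of 48 and 1 of 6 of Rhbdl1. They held 16 of 35 and 2 of 6 reads of Coro7, 51 of 66 and 0 of 10 of Git1, and 14 of the 60 Pdap1 reads of replicate 2. Klhl10 had 45 and 1 reads, of which 44 in replicate 1 lay on single-exon Genomic models. So did all reads of AC154200.1 (0 and 118 reads) and D130009I18Rik (0 and 99 reads). Gm6969 (108 and 5 reads), Rps4x-ps (0 and 95 reads) and Gm29216 (0 and 78 reads) are pseudogenes. Mir1906-1 (0 and 55 reads) lies within Meg3, and Gm49450 (1 and 102 reads) overlaps Tuba1a and Tuba1b and had a log2 ratio of -0.56 once overlapping genes were counted together. Of 11650 genes with 10 or more reads over both libraries, 4091 passed an adjusted p of 0.05 (Fisher's exact test between the 2 libraries, 4961 at an unadjusted p under 0.05): 1510 were higher in replicate 2 and 2581 lower. The direction of this split depends on the scaling, with 1981 higher and 1328 lower with TMM and 2022 higher and 1290 lower with DESeq2 size factors. The count was 2337 with a minimum of 2-fold. Log2 levels correlated across genes, which are not independent replicates, with r = 0.848, and in 1805 genes with 100 or more reads in each library the median absolute log2 ratio was 0.49, against 0.09 from counting alone.

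Short transcripts were higher in replicate 2 and long ones lower. The median log2 ratio was 0.45 in the shortest of 5 length groups of genes (transcripts up to 1434 nt), where 795 genes were higher and 175 lower, and -0.28, -0.39, -0.49 and -0.40 in the other groups in order of length. The group with transcripts of 3007 to 4176 nt had 110 genes higher and 674 lower. Apoa2, Ttr and the brown fat gene Cox8b (5.43-fold higher) have short transcripts, while Dab2 and Soat1 (0.414 times) have long ones, but Malat1, with 6983 nt, was higher. Among ERCC spike-ins, synthetic RNAs added to each sample, all 8 shorter than 900 nt were higher in replicate 2 relative to all spike-in reads and 14 of 16 longer ones were lower, from a log2 ratio of 2.27 to -2.06. Across 11026 genes Spearman's rho of log2 ratio with length was -0.30, and -0.31 given GC content. Over the 24 spike-ins with 10 or more reads in each library rho was -0.731 (permutation p = 0.00013, two-sided) and Pearson's r was -0.89 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted over the 2 tests 2e-05), and r was -0.84 without the 2 lengths farthest from the median. The spike-in lengths form separate groups, and the relation rests on the difference between them: over the 16 longer spike-ins rho was -0.12 (permutation p = 0.65).

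**Figure D2:**
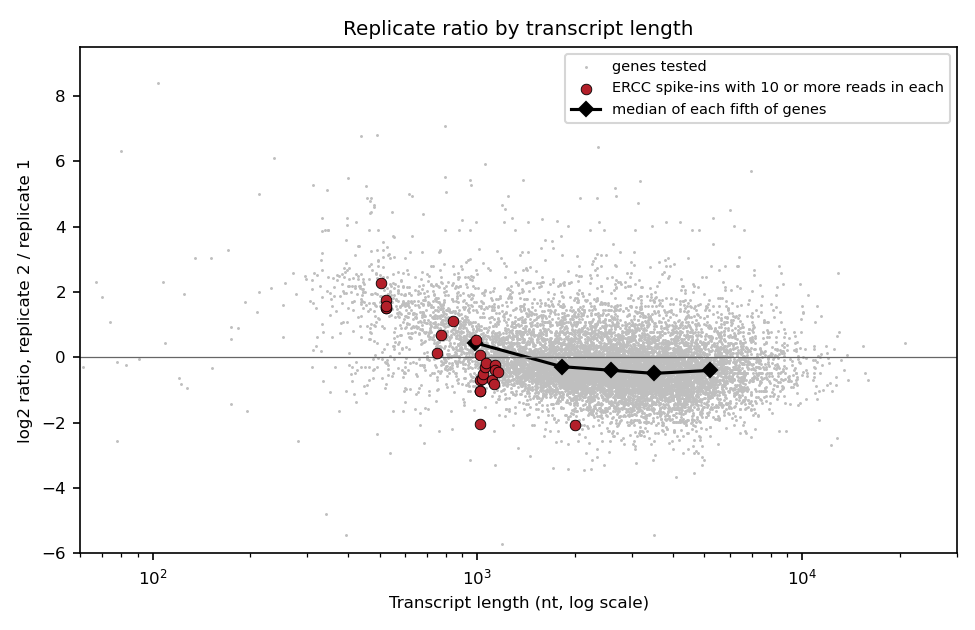
Log2 ratio of replicate 2 over replicate 1 against transcript length in nt (log axis) for tested genes (grey), ERCC spike-ins with 10 or more reads in each library, and medians of 5 length groups of genes. Short transcripts lie above 0 and long ones below, in genes (medians 0.45 to -0.49) and in spike-ins (2.27 to -2.06); genes outside the plotted range are left out.

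The replicates differed in their shares of single-exon reads and of reads that match an annotated transcript in full. Single-exon fragments here are single-exon ISM or Genomic models. They need not be unspliced RNA, since a short piece within 1 exon also lacks introns. Such fragments took 12.6% of Cyp11a1 reads in replicate 1 (95% Clopper-Pearson interval 11.8 to 13.4%). In replicate 2 they took 53.9% (52.9 to 54.9%). The main fragment of replicate 1 ran from 58026694 to 58027023 (ISM, 867 reads). That of replicate 2 ran from 58024312 to 58027023 (Genomic, 5222 reads). Its span is longer than the spliced transcript of 2120 nt, so it includes intronic sequence, and the 2 shares hold unlike models. Single-exon fragments took 23.5% (21.4 to 25.7%) and 54.3% (53.3 to 55.3%) of the reads of Ahsg. They took 13.3% (12.2 to 14.5%) and 28.0% (27.3 to 28.7%) of those of Apoe, and 10.99% (10.0 to 12.0%) and 19.4% (18.2 to 20.7%) of those of Star. Alb, Trf and Th had 0.021%, 0.054% and 0.093% of such reads in replicate 1 and 0.388%, 0.463% and 2.46% in replicate 2. Over all annotated genes such fragments took 3.62% (3.58 to 3.66%) and 10.11% (10.06 to 10.16%) of reads. All single-exon models, annotated ones included, took 6.53% (6.48 to 6.58%) and 14.3% (14.2 to 14.4%). Annotated transcripts matched in full (Known) took 73.8 ± 5.11% of all reads outside spike-ins, 77.5% (77.4 to 77.5%) in replicate 1 and 70.2% (70.2 to 70.3%) in replicate 2.

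Incomplete splice matches (ISM), which hold part of an annotated intron chain, took 10.5 ± 2.70% of reads, and models within genes that are mostly single-exon (Genomic) took 4.58 ± 2.99%. Both shares were larger in replicate 2: 8.60% and 12.4% for ISM, and 2.47% and 6.70% for Genomic. Models with an unannotated combination of annotated splice sites (NIC, 4.07 ± 1.32%) or an unannotated splice site (NNC, 3.13 ± 0.634%) had smaller shares in replicate 2. Reads antisense to genes made up 2.57% (2.53 to 2.60%) and 4.09% (4.06 to 4.12%), and reads between genes 0.318% (0.307 to 0.330%) and 0.729% (0.715 to 0.743%). No test between groups exists here; each difference exceeded the 95% counting intervals of both libraries. The line between ISM and Genomic is not sharp, since overlapping single-exon fragments of 130 of 482 genes were put in different classes in the 2 libraries. Together the classes took 11.1% and 19.1%.

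**Figure D3:**
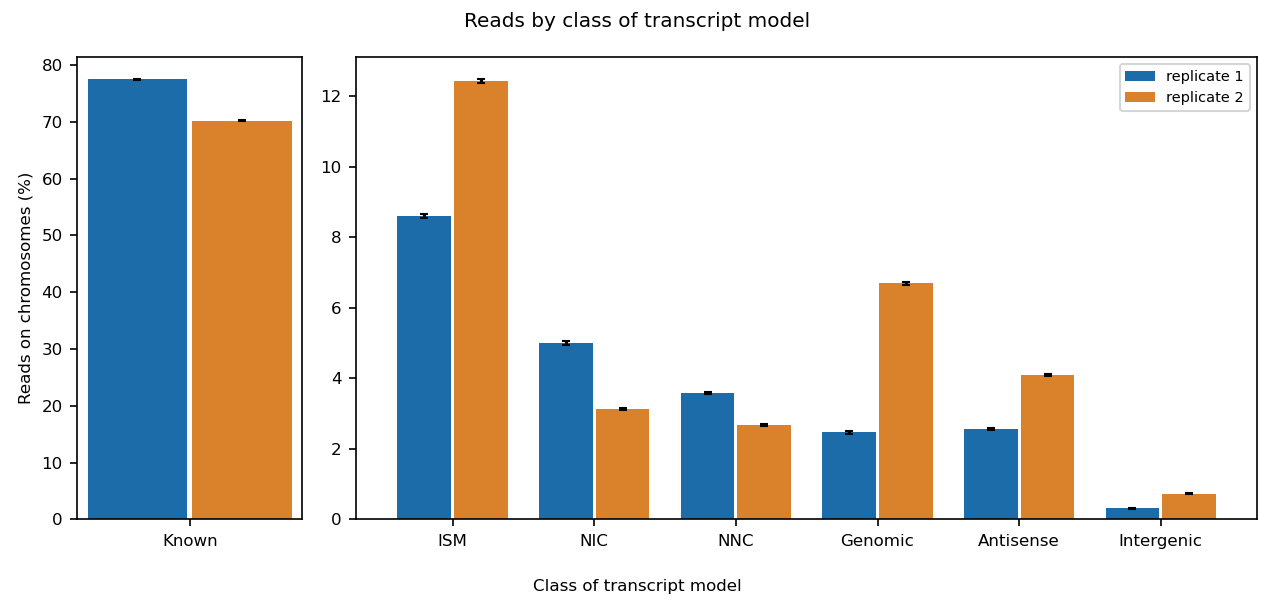
Percent of reads outside spike-ins in each transcript class per library, in 2 panels with separate scales; bars are Clopper-Pearson 95% intervals. Known takes 77.5% in replicate 1 and 70.2% in replicate 2, and the ISM, Genomic, Antisense and Intergenic shares are larger in replicate 2.

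A single annotated isoform was dominant in most genes: of 4781 genes with 20 or more annotated reads in each library, 3430 gave 90% or more of these reads to the leading isoform in both. Of the 4781, 3040 had reads on 2 or more annotated isoforms. The rest had reads on 1 alone and count among the 3430 by construction. Cyp11a1-201 held all but 1 of the annotated reads of Cyp11a1 (5152 and 3706 reads), and the leading isoforms of Fdx1 (99.0 ± 0.698%), Fdxr (99.6 ± 0.170%), Nr5a1 (95.8 ± 2.25%), Hsd3b6 (95.4 ± 0.967%), Mrap (93.6 ± 1.51%), Soat1 (93.2 ± 4.40%) and Scarb1 (90.3 ± 0.931%) took at least 90% of their gene's annotated-transcript reads on average. Of the steroidogenesis genes with more than 1 isoform, the hormone-sensitive lipase Lipe was divided, with 57.0 ± 3.01% in Lipe-202 and 26.1 ± 2.63% in Lipe-201. The medullary genes Scg2 and Scg3 were divided too: Scg2-201 took 52.6 ± 4.98% and Scg2-202, with an additional intron, 47.4 ± 4.98%, and Scg3-202 took 60.1 ± 5.86%. Snap25-202, which like Snap25-201 has 8 exons, took 72.9 ± 5.63% of 29 and 26 annotated reads.

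Of the 4781 genes, 490 (10.2%) gave 20% or more to a second isoform in both. With replicate 1 or replicate 2 taken alone 745 and 751 genes did, out of the wider sets that reach the read minimum in that library. The most-read of these genes included Cox4i1, Hadhb, Acly, Atp5c1 and Mtch1 of energy and lipid metabolism, the chaperone Hspa5, the apolipoprotein gene Apoa2 and Cnbp, Eif4h, Ifi27, Ybx3, Ptp4a1, Aplp2 and Impdh1. Their leading isoforms took from 35.9 ± 1.67% (Impdh1) to 79.6 ± 0.138% (Ptp4a1). Hadhb-203 and Hadhb-201 took 50.4 ± 0.470% and 47.3 ± 0.225%. Pkm-201 took 79.4 ± 2.34% of the annotated reads of pyruvate kinase Pkm and Pkm-202 20.6 ± 2.34%, and Gnas-208 took 63.6 ± 1.90% of the annotated reads of Gnas. The leading isoform was the same in both libraries in 4668 of the 4781 genes (97.6%) and in 395 of the 490. Of the 4781, only 3040 had reads on 2 or more annotated isoforms, and the rest agree by construction.

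**Figure D4:**
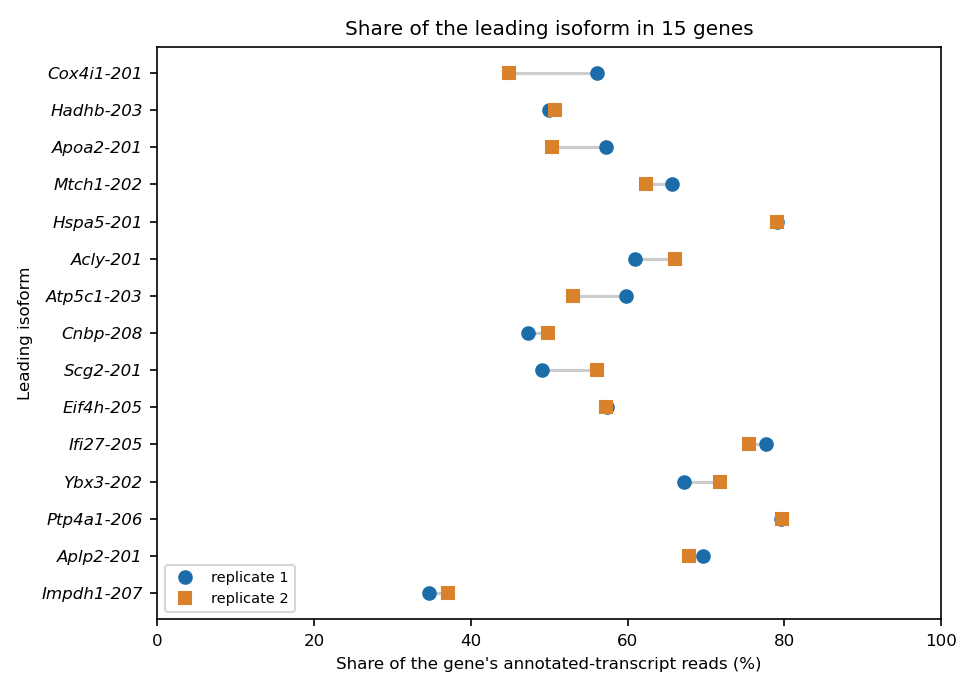
Percent of annotated reads in the leading isoform of the 15 most-read genes with 2 or more isoforms in use, per library. The shares run from 34.7% and 37.1% for Impdh1 to 79.5% and 79.7% for Ptp4a1, and Cox4i1 differs most between the libraries (56.1% and 44.9%).

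Isoform shares differed between the libraries in few genes. The muscle and cytoskeleton gene Tpm1 gave 66.7% of 147 annotated reads to Tpm1-205 in replicate 1 and 85.4% of 534 in replicate 2 (adjusted p = 0.000169, Fisher's exact test), and Tpm3 gave 99.7% and 89.6% to Tpm3-201 (adjusted p = 1.26e-05, exact). Cox4i1, a subunit of cytochrome oxidase, gave 56.1% and 44.9% to Cox4i1-201 (adjusted p = 3.85e-10, exact). Tpm2 (55.2% and 70.5%) and Scg2 (49.1% and 56.1%) did not pass (exact adjusted p = 0.294 and 0.199). Of 3040 genes with 2 or more isoforms, 62 passed, 281 had an unadjusted p under 0.05, and 54 of the 62 differed by 10 percentage points or more. In 37 of the 62 the leading isoform gained share in replicate 2 if shorter than the second isoform, or lost share if longer. These were 59.7% (interval 46.5 to 71.9%, exact binomial p = 0.162, two-sided).

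Unannotated splice patterns made up most reads of several genes in both libraries. Oaz1, which encodes the antizyme that limits polyamine synthesis, had 1370 and 1859 reads in 1 NIC intron chain on chromosome 10 (80826656 to 80829284), 95.6 ± 1.37% of its reads, and Phb2 (94.6 ± 2.16%), Mpc1 (95.2 ± 1.14%), Oaz2 (84.9 ± 0.562%), Cd47 (59.0 ± 3.20%), Ctbp1 (58.8 ± 2.75%), Ptov1 (41.0 ± 2.73%), Hnrnpk (36.9 ± 6.66%) and Cdkn1c (27.7 ± 0.512%) followed. In the medulla gene Cyb561, which encodes an electron carrier of chromaffin granules, a NIC chain of 6 exons took 53.7 ± 0.024% (282 and 175 reads). Among these NIC chains, those of Mpc1 and Hnrnpk have 1 unannotated intron each. In the others every intron is annotated and only their combination is not, so they need not be transcripts of a new kind. In Penk, the precursor of enkephalins, an NNC chain with an unannotated intron on chromosome 4 from 4138147 to 4138634 took 51 of 54 and 50 of 52 reads (95.3 ± 1.21%).

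Of the NNC chains with most reads in both libraries, those of Pitpna (88.2 ± 4.89%), Capn2 (85.8 ± 1.07%), Cct6a (84.7 ± 1.18%), Chmp1a (83.1 ± 8.74%), Atp2a1 (72.4 ± 11.2%), Idh3g (68.3 ± 11.2%) and Txnrd2 (67.4 ± 3.77%) took more than all other models of the gene together in both libraries. That of Col6a1 did so in replicate 2 alone (49.4% and 61.4%), and those of Dctn2 (37.9 ± 3.80%) and Cdkn1c (9.15 ± 0.148%) in neither. The Idh3g chain has 1 unannotated intron, on chromosome X from 73782104 to 73782670, with 419 and 557 reads. In the steroidogenic genes unannotated chains were minor: the largest in Cyp11a1, Cyp21a1, Cyp11b1, Hsd3b1 and Star took 0.902 ± 0.532%, 1.21 ± 0.314%, 0.920 ± 0.115%, 0.599 ± 0.015% and 0.213 ± 0.011% of reads, and those in Fdxr, Cyp11b2, Nr5a1 and Scarb1 took 6.55 ± 0.008%, 3.36 ± 1.56%, 2.95 ± 0.370% and 0.409 ± 0.118%. Chga and Th had chains of up to 0.376 ± 0.093% and 0.326 ± 0.066%.

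In all, 6352 of 31043 NIC chains (20.5%) and 4391 of 39876 NNC chains (11.01%) were seen in both libraries, 10743 chains in 5033 genes, against 15465 of 23396 annotated chains (66.1%). With 5 or more reads in each library 1128 chains in 862 genes were left. Redetection depended on depth: of NNC chains with 1 read in replicate 1, 12.5% (12.0 to 13.0%) were found in replicate 2, against 47.1% (45.6 to 48.5%) of annotated chains, and of those with 10 or more reads 99.0% (96.5 to 99.9%) and 99.5% (99.3 to 99.7%) were. In the libraries 1495 chains were classed differently. The sequence at the splice sites was not analysed here.

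**Figure D5:**
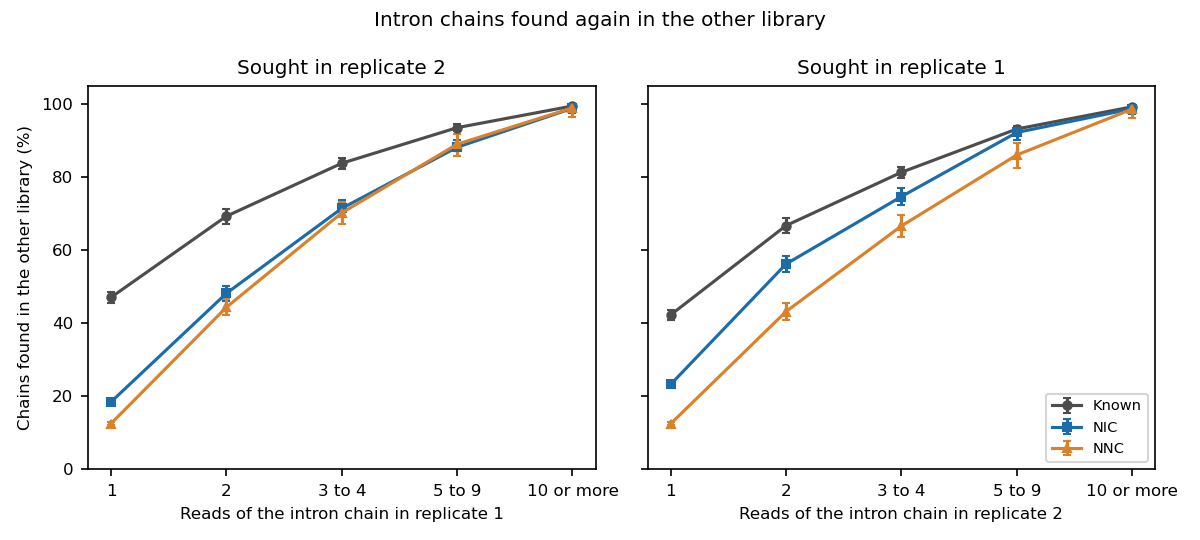
Percent of intron chains of one library found in the other, by reads in the first library, for Known, NIC and NNC chains; bars are Clopper-Pearson 95% intervals. Chains with 1 read in replicate 1 were found again for 47.1% of Known, 18.4% of NIC and 12.5% of NNC, and its chains with 10 or more reads for 99.5%, 98.9% and 99.0%.

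Among loci not assigned to annotated genes, the one with most reads lay on chromosome 17 from 39843013 to 39848035 on the minus strand, with 3133 and 2886 reads. It overlaps Gm26917 and Gm42418 on the other strand and CT010467.1 and AY036118 on the same strand. This is a region of ribosomal RNA repeats where the placement of reads is uncertain. Others with many reads were antisense to Sept2 (chromosome 1 from 93507858, 317 and 282 reads), to the pseudogene Tmem250-ps (chromosome 2 from 26136814, 215 and 304 reads) and to Ywhaz (chromosome 15 from 36770279, 170 and 351 reads). Of 8648 antisense loci of replicate 1, 4864 overlapped one of replicate 2 on the same strand, and 703 of 1564 intergenic loci did.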

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

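The strand test below was chosen after its result was seen. ERCC spike-ins, which have no antisense transcript, carried 150 antisense reads in replicate 1 (0.976%, Clopper-Pearson interval 0.827 to 1.14%) and 365 in replicate 2 (1.03%, 0.925 to 1.14%), above the 3 reads that a count of 0 allows. Unplaced contigs carried 296 reads in replicate 1 and 717 in replicate 2. The gene comparisons kept the annotated genes among them and left out the unannotated loci. The contig reads included AC149090.1 (147 and 164 reads), CAAA01118383.1 (71 and 73 reads), Tmlhe (34 and 35 reads) and Vamp7 (10 and 13 reads), and a single unannotated locus held 320 of those of replicate 2.

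Replicate 2 held more antisense and Genomic reads than replicate 1 and fewer NIC and NNC reads. Reads placed on the wrong strand are argued against as the whole source of the antisense reads, since the antisense share on chromosomes (2.57% and 4.09%) lay at least 1.42 percentage points above the upper bound of the spike-in share in both libraries. A few loci did not hold most Genomic reads: 10 genes held 21.3% of those of replicate 2, and 3 of them 16.1%. A length preference that acts between genes is argued against as the source of the NIC and NNC difference. Their share of spliced reads was 2.12 percentage points higher in replicate 1 with 20 gene-length bins weighted equally (9.76% and 7.63%), and higher in 20 of the 20 bins. Bins of gene length cannot decide on a preference among long and short molecules of the same gene. What stays open is a length preference within genes or a difference in RNA integrity, nuclear RNA content or library preparation, none of which was tested. No biological explanation was tested because the design has 1 group.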

How the results depend on the processing

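Results with settings chosen after the data were seen are those that use transcript length or GC content, the merged ISM and Genomic classes, merged intron chains, overlapping genes counted together, the counts without single-exon models and the levels without the liver, brown fat and muscle lists. The number of genes at 10 CPM or more ran from 7787 to 9375, with 16 to 20 of the top 20 genes shared. Of the single-gene ratios between replicates over all settings, 906 values kept the call or its absence, and the called ones among them kept direction. Another 61 kept direction and lost the call, 26 gained a call in either direction, and 16 of genes called as reported reversed. A change of sign in a gene not called as reported was not counted as a reversal. The reversed log2 ratios were, with TMM, Nr5a1 0.019, Car3 0.18 and Scarb1 0.11; with DESeq2 size factors, Nr5a1 0.031, Car3 0.20 and Scarb1 0.12; with annotated models only, Mc2r -0.05; with the ratio expected from transcript length, Fdxr 0.009, Atp5a1 0.018, Nr5a1 0.21, Car3 0.16, Fdx1 -0.28, Scarb1 0.24 and Fabp4 -0.35; without single-exon models, Car3 0.001; and with overlapping genes counted together, Gm49450 -0.56. The scalings add a constant to every log2 ratio, which shows their cause; the cause of the other reversals was not tested.

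With models of 5 or more reads, Known took 82.6% of reads, ISM 7.79%, NIC 2.27%, NNC 0.992% and Antisense 2.20%, since models with few reads are left out. The 4091 genes that differ became 2337 with a 2-fold minimum and 2694 with the ratio expected from length. Among the gene lists, percentiles crossed the middle 95% with members of 50 or more reads (steroidogenesis 6.01, chromaffin medulla 0.0, endothelium 1.43), with annotated models only (chromaffin medulla 0.205, endothelium 2.13), after removal of length and GC trends (steroidogenesis 6.98, zona fasciculata 1.65, X-zone 2.13, chromaffin medulla 1.57, macrophage 94.2) and with length-matched random lists (erythroid 92.4, immediate early and stress 98.8); the cause was not tested. Zona glomerulosa and liver kept their side in every setting run, and TMM cannot move a percentile because it shifts all genes alike.

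The 490 genes with 2 or more isoforms in use became 257 with 50 reads, 865 with a 10% share and 745 to 751 with either replicate left out, since fewer genes or fewer conditions apply, and the 62 usage differences ran from 46 to 82. The 10743 unannotated chains in both libraries became 3904 with 2 or more reads in each, 1128 with 5 or more, 6352 for NIC and 4391 for NNC, each a part of the total by construction. Depth limits the rest: by simulation with counting noise alone, a 2-fold difference was called in 36.0% of genes and a shift of 10 percentage points in isoform share in 26.9%.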

Other observations

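The bone and neutrophil granule lists were chosen after most of their values were seen, and the length split of spike-ins after the plot was seen; the other tests of this part were set before their results, with the muscle list including 3 genes already seen. Replicate 2 held transcripts of bone and of neutrophil granules that had 0 or few reads in replicate 1. Bglap (0 and 77 reads), Ibsp (0 and 20 reads), which encodes bone sialoprotein, and Mmp9 (0 and 29 reads) had no reads in replicate 1, where a count of 0 allows 3, and Spp1 was 6.64-fold higher in replicate 2. Of 10 tested bone genes 8 were higher and 1, Phospho1, lower (0.316 times); the 8 include Col1a1 of the capsule list. Of 8 tested neutrophil granule genes S100a8 (5 and 46 reads), S100a9 (2 and 40 reads) and Camp (3 and 22 reads) were higher and 0 lower, and 1 was higher against the ratio expected from transcript length.

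Skeletal muscle transcripts were also higher in replicate 2. Of 17 tested genes 13 were higher and 0 lower, among them the skeletal actin Acta1 (2.69-fold, 432 and 1631 reads), the creatine kinase Ckm (2.81-fold), the troponin Tnnc2 (5.85-fold) and the myosin light chain Mylpf (9.62-fold), and their sum was 1252 CPM in replicate 1 and 4028 CPM in replicate 2. The 13 further brown fat genes were divided, with 6 higher, such as Cox8b (5.43-fold) and Cox7a1 (3.88-fold), and 4 lower, such as Cpt1b (0.546 times) and Dio2 (0.379 times).

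Liver transcripts were abundant in both libraries (Alb at 5054 and 8696 CPM) and higher in replicate 2. A candidate explanation is liver RNA in the samples: of 30 further hepatocyte genes 90% had 10 CPM or more in both libraries, 23 of 28 tested were higher in replicate 2 and 2, Tat and Mat1a, were lower (0 with TMM scaling), which the same excess would not give, and Cyp2c29 had 2 reads in each library; how many of these genes the adrenal itself expresses cannot be counted from these libraries. The difference in length preference is argued against, since the liver list lay at percentile 99.99 of random lists matched on expression and length. Whether the same excess carried skeletal muscle and brown fat along stays open: after removal of the length trend muscle lay at percentile 100, which goes with it, and brown fat at 72.3, but the brown fat genes went both ways (6 higher, 4 lower), so that their median does not decide. Neighbouring tissue in the dissection, reads carried over from libraries of other tissues and a true difference between animals also stay open and were not tested.

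Short transcripts were higher in replicate 2. A length preference of library preparation or sequencing is consistent with the spike-ins, whose log2 ratio fell with length (rho = -0.731, 24 spike-ins), through the contrast between those under and over 900 nt. The genes did not follow the spike-ins closely: per doubling of length the log2 ratio changed by -2.1 in spike-ins (95% interval -2.42 to -1.84) and by -0.85 in the 3626 genes of the same length range. Truncation of tissue RNA at the 5' end in replicate 2 may add to it. The excess of 5'-truncated reads in replicate 2 was 0.85 ± 0.31 percentage points (95% interval) larger in the longest of 5 length groups of genes than in the shortest. It was not ordered by length (0.739, 3.80, 2.11, 3.47 and 1.59 points from the shortest group to the longest). The label of truncated reads was not equal in the 2 libraries, which leaves these values uncertain. The main model of Hsd3b1, a gene of the second group, was left out in replicate 1 (4050 reads) but counted in replicate 2 (2949 reads). GC content is argued against as the cause, since the partial rho with length given GC was -0.309. The share of each source stays open, and no biological explanation was tested because the design has 1 group.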
